A study of Mus musculus with 12 samples.

How the data were processed

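RNA was measured in trigeminal ganglia (TG), which hold the cell bodies of sensory neurons of the face and jaw, and in the spinal trigeminal nucleus caudalis (Sp5C), the brainstem nucleus that receives pain and temperature input from those neurons. The animals were C57BL/6 mice, an inbred laboratory strain, 8 weeks old per the labels. The sample titles gave 4 groups, STG, CTG, SSp5C and CSp5C, with 3 numbered libraries each. The labels do not say what the letters S and C stand for, so the letters were used as they stand and every contrast between them is given as C minus S. Nor do the labels say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

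Per the labels' protocols, RNA was extracted with Trizol, 3 µg of total RNA entered each library, ribosomal RNA was removed with a Ribo-zero kit, and stranded libraries were prepared with the NEBNext Ultra Directional kit. Such libraries hold RNA with and without a poly(A) tail. The submitters' processing notes name the aligner HISAT2 (version not given in the sources used here), the assembler StringTie 1.3.1 and Cuffdiff 2.1.1. The genome build and the annotation used upstream are not given in the sources used here.

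The authors deposited FPKM values (fragment numbers scaled to transcript length and library size) in 3 tables, each with a value for every transcript and library. The deposited FPKM tables held 57109 protein-coding transcripts of 21981 genes, 2789 annotated long non-coding RNA (lncRNA) transcripts of 2315 genes, and 5602 lncRNA transcripts of 5150 loci that were assembled from the reads and carry no gene name. Because the values are already scaled, the number of reads behind a value, and with it the depth of each library, is unknown. No interval for counting error can be given. The FPKM of all 3 tables summed to between 412454 (STG replicate 1) and 511982 (SSp5C replicate 1) per library. A single assembled locus took between 25.8% (STG replicate 1) and 41.3% (SSp5C replicate 1) of that sum. Despite this, the libraries were close in scale over protein-coding genes, with median ratios to the mean library between 0.969 and 1.02.

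The FPKM of a gene's transcripts were summed. Log2 values were taken after adding a pseudocount of 1 for protein-coding genes and 0.5 for lncRNA, so differences are on the log2(FPKM + pseudocount) scale, which understates the change of low genes. Genes entered a comparison with a mean FPKM of at least 1 (protein-coding) or 0.5 (lncRNA) over the libraries compared. Differences were tested with limma 3.58.1 in R 4.3.3 (linear models with a mean-dependent prior and robust moderation), two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The tables were read with the data.table package, version 1.17.8. Group means of FPKM are given ± SD, with n = 3 libraries per group for C against S and n = 6 libraries per tissue for TG against Sp5C. Each C against S comparison used the 6 libraries of its tissue. The difference of both C against S effects, the average of both, and the contrast of TG with Sp5C used all 12 libraries. A gene listed at 0 in a whole group is described only as listed at 0, with the value of each library, because an exact 0 in an FPKM table can be a failed estimate.

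Gene lists of cell types, pathways and neighbouring tissues, 64 in all, were written from general knowledge before the data were examined, as were the groups, the main tests, the rule for naming genes and most alternatives. A list was tested where at least 5 members passed the filter, with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. Camera asks whether a list moved relative to the other genes, whereas fry asks whether its members moved on balance in one direction. For each list the number of members past the threshold is also given after adjustment over the list alone. The comparison over both tissues, the tissue contrast of effects for annotated lncRNA, and the removal of libraries or of genes listed at 0 throughout a group were added after the data were seen.

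Genes were named by a rule. For C against S, the 10 highest and 10 lowest differences among genes that passed and whose groups did not overlap were taken, and a direction with fewer was filled up to 10 by the smallest p, with the added genes reported as not passing. By the same rule, the tissue contrast took 15 in each direction and each lncRNA comparison 5. The test of the difference of effects took the 5 smallest p in each direction. Lists that camera called gave up to 4 members with the smallest p, and other lists at most 2. Calca, Tac1, Trpv1, Atf3, Fos, Gfap, Aif1, Il1b, Ccl2 and Ptgs2 were always looked up, as were Malat1, Neat1, Meg3, Miat and Snhg11 among lncRNA. Of these, Ptgs2 lay under the filter in both tissues, Trpv1, Atf3, Il1b and Ccl2 lay under it in Sp5C, and no value is reported for Meg3 and Snhg11. Not every gene the rule admits is described, some genes are not reported here, and the remainder are summarised by number. Coordinates are those of GENCODE M21 on GRCm38, matched by gene identifier. A match was found for 21951 of the 21981 protein-coding genes and 2301 of the 2315 annotated lncRNA genes, and for 0 of the assembled loci, whose positions are therefore not given. Values of genes that share sequence with close copies, such as ribosomal protein, histone and Gm-numbered genes, are uncertain, because it is not known how shared reads were divided.

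The tests were checked on simulated libraries with the means and spread of the real ones. Each gene's noise was drawn from its moderated variance, independently of the others. Changes were placed only in genes with a mean log2(FPKM + 1) of at least 2, so the shares do not cover lower genes. In each simulation, 67 genes were changed by 0.5, 67 by 1 and 66 by 2 at once. The Benjamini-Hochberg adjustment is more lenient when many genes change. The shares therefore do not give the power of the real C against S tests, where few genes passed. For TG, with 12906 genes simulated, 56.7% of genes changed by 0.5 on the log2 scale were recovered, 91.0% of those changed by 1 and 95.5% of those changed by 2, and 8 unchanged genes were called. For Sp5C, with 12690 genes, the shares were 56.7%, 95.5% and 97.0%, with 7 unchanged genes called. For TG against Sp5C, with 13081 genes, 94.0%, 95.5% and 100% were recovered and 7 unchanged genes were called. A simulated list of 15 genes raised by 0.5 was recovered in TG and in Sp5C, with 0 other lists called. Without correlation between simulated genes, this does not show how often lists of correlated genes are called. The estimated correlation of real genes was 0.951 for the pituitary list in TG.

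Alternatives covered the pseudocount, the filter, median-ratio scaling, quantile normalization, library weights, moderation without trend, the replicate number as a block, single transcripts as features, a fit of all 12 libraries, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.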

Results

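Gene expression was measured by total RNA sequencing in the trigeminal ganglia and the spinal trigeminal nucleus caudalis of mice, in a series on lasting inflammatory pain of the jaw joint. There were 12 libraries in 4 groups of 3, STG and CTG from ganglia, SSp5C and CSp5C from the brainstem nucleus. Tissue separated the libraries far more than the letter did. Over protein-coding genes, libraries of one group correlated at r = 0.974 to 0.989, libraries of one tissue with different letters at 0.967 to 0.988, and libraries of different tissues at 0.765 to 0.803. The first principal component, which parted the tissues, held 85.8% of the variance, and the next held 3.14%. No library's values were a copy of another's, since at most 0.0115% of the values above 0 were identical. This does not show that the libraries came from separate animals. The FPKM tables give no read numbers, so the depth of each library is unknown.

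The contrast of TG with Sp5C compares the peripheral ganglion with its central target and shows whether each dissection holds the cells its label names. Among the genes with the highest differences were several of myelinating Schwann cells and of pain-sensing neurons. Prx, periaxin of peripheral myelin, stood at 218 ± 20.9 FPKM in TG and 0.746 ± 0.486 in Sp5C (SD, n = 6 libraries each, log2 difference 7.01). Avil, an actin-binding protein of sensory neurons, stood at 196 ± 23.3 against 0.506 ± 0.27. The nociceptor sodium channels Scn10a (114 ± 7.91 against 0.228 ± 0.265) and Scn11a (58.3 ± 5.15 against 0.0879 ± 0.0626), Pirt, a regulator of Trpv1 (140 ± 10.1 against 1.07 ± 0.361), and Ngfr, the low-affinity neurotrophin receptor (147 ± 14.1 against 2.3 ± 0.495), were higher in each TG library than in each Sp5C library. Log2 differences of Fxyd2 (6.55), Tusc5 (6.51), Trappc3l (6.41), Tmem233 (6.10), Plekha4 (6.02), Ppp1r1c (5.82), Cldn19 (5.79) and Ncmap (5.49) were also among the highest 15.

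Genes of inhibitory transmission, of astrocytes and of hindbrain position were higher in Sp5C. Glra1, a glycine receptor subunit, stood at 0.0705 ± 0.0581 FPKM in TG and 90.8 ± 7.52 in Sp5C (log2 difference −6.42), and Slc6a5, the neuronal glycine transporter, at 0.0828 against 67.1 ± 4.26. The GABA-synthesising enzyme Gad1 stood at 0.248 against 70.3 ± 4.31, and Slc32a1, the vesicular transporter of GABA and glycine, at 0.0483 against 55.2 ± 4.06. Slc12a5, the neuronal chloride exporter, stood at 0.323 against 85.4 ± 13.9, Slc1a2, the main glutamate transporter of astrocytes, at 4.84 ± 1.37 against 248 ± 21.4, and Penk, the enkephalin precursor, at 0.939 ± 0.497 against 58.9 ± 8.73. Hoxb5, a hindbrain and spinal cord patterning gene, stood at 0.0101 against 34.3 ± 5.56. The other lowest differences were those of Lamp5 (−5.85), Slc6a11 (−5.57), Gad2 (−5.23), Grin2a (−4.80), Hoxa5 (−4.78), Htr2c (−4.74) and Rasgrf1 (−4.72).

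In limma's test of 13081 genes, 4739 were higher and 4575 lower in TG, of which 1285 and 1183 differed by at least 1 on the log2(FPKM + 1) scale. The largest adjusted p of the genes named was 1.24e-10. Each had all 6 libraries of one tissue above all 6 of the other, which the rule for naming them asked for. Over all genes, the tissues did not overlap for 53.7%, against 0.216% by chance.

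**Figure D1:**
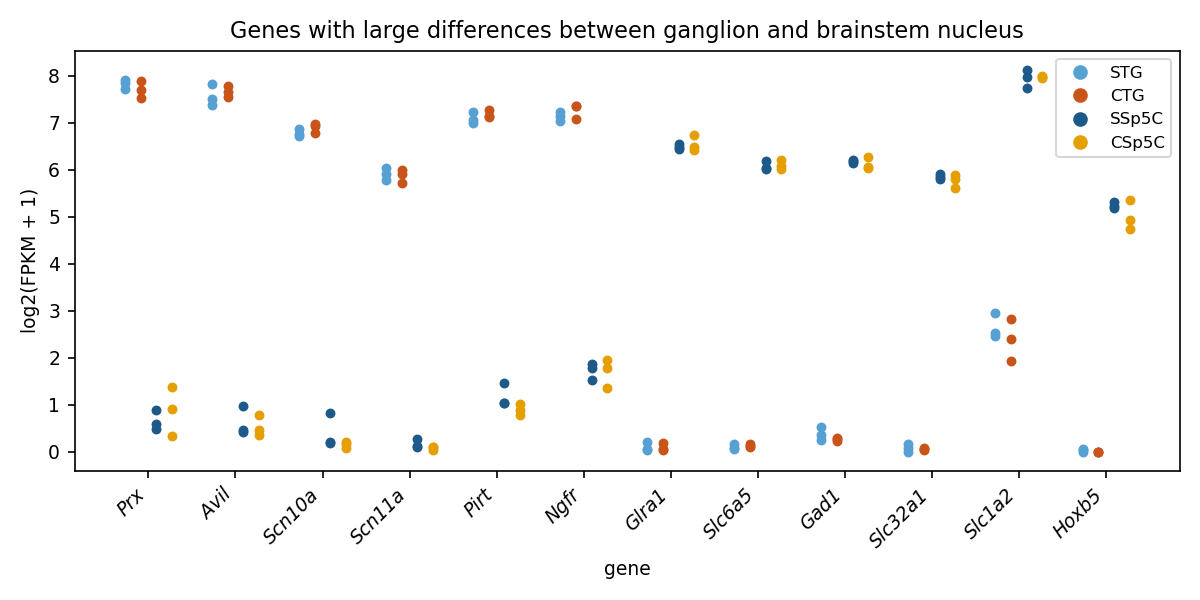
Expression of 12 of the named tissue genes as log2(FPKM + 1), one point per library, coloured by group. The TG libraries lie above the Sp5C libraries for Prx (log2 difference 7.01), Avil, Scn10a, Scn11a, Pirt and Ngfr and below them for Glra1 (−6.42), Slc6a5, Gad1, Slc32a1, Slc1a2 and Hoxb5.

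The comparison of CTG with STG asks what differs in the ganglion between the letters. Epg5, an autophagy gene (ENSMUSG00000039840, chromosome 18, 77938465 to 78035013, plus strand), was listed at 0 in all 3 STG libraries and at 3.27, 3.59 and 3.71 FPKM in CTG. It was the sole gene of 12906 to pass limma's test (adjusted p = 0.00293), but not in the fit of all 12 libraries (0.590). It was also at 0 in all SSp5C libraries and at 4.32, 0 and 4.31 in CSp5C. Without CTG replicate 2 or 3 its adjusted p was 0.0773 or 0.0525. A total of 606 genes had an unadjusted p under 0.05, and the groups did not overlap for 10.8% of genes, against 10% by chance. Without CTG replicate 1, 7 genes passed, without STG replicate 2, 3, and without CTG replicate 2 or 3, 0.

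The genes next in rank included both metallothioneins, which bind zinc and copper and are induced by glucocorticoids. Mt1 stood at 65.0 ± 4.93 FPKM in CTG and 37.4 ± 0.966 in STG (adjusted p = 0.0813, log2 difference 0.78) and Mt2 at 64.4 ± 9.67 against 31.2 ± 2.78 (0.18, 1.01), with all CTG libraries above all STG libraries. Without CTG replicate 1 they passed the test, at adjusted p = 0.0191 and 0.0456. Slc38a10, an amino acid transporter, stood at 23.9 ± 0.125 against 17.4 ± 0.528 (adjusted p = 0.18) and Slc6a8, the creatine transporter, at 21.5 ± 0.643 against 15.1 ± 0.821 (0.207). Fstl3 (3.95 ± 0.461 against 2.52 ± 0.072), Rps27 (161 ± 33.5 against 78.7 ± 16.9), Ms4a4a (1.87 ± 0.0933 against 0.916 ± 0.222), Ibsp (4.93 ± 1.3 against 2.32 ± 0.31) and Cda (14.2 ± 1.48 against 10.3 ± 0.731) had adjusted p of 0.871 to 0.917. With lower means in CTG, Ap5s1, a subunit of an endosomal adaptor complex, stood at 2.71 ± 0.192 against 5.37 ± 0.244 and Prokr2, a prokineticin receptor, at 2.03 ± 0.077 against 4.53 ± 0.428 (adjusted p = 0.11 each). Dgcr2 (15.3 ± 1.23 against 21.9 ± 0.847), Apbb2 (14.2 ± 2.91 against 26.6 ± 0.944) and Sh2d4b (1.37 ± 0.238 against 2.86 ± 0.0292) had adjusted p of 0.429 to 0.461. Gm12355, Zfp950, Pcdh19, Cyp4f17 and Platr25 had adjusted p of 0.569 to 0.615.

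Genes often followed in pain studies did not pass in TG. The peptide precursors Calca (345 ± 41.9 FPKM in CTG, 301 ± 11.1 in STG) and Tac1 (136 ± 8.64, 130 ± 20.4), the heat and capsaicin channel Trpv1 (12.5 ± 1.75, 11.3 ± 0.892), the injury gene Atf3 (2.36 ± 0.574, 1.88 ± 0.478) and the activity gene Fos (2.62 ± 0.232, 3.33 ± 1.75) differed by less than the test could separate from the spread (adjusted p of 0.96 to 0.994). So did Gfap (28.6 ± 15.4, 29.2 ± 1.48), Aif1 of macrophages (3.89 ± 1.49, 3.88 ± 0.742), Il1b (2.94 ± 4.59, 0.343 ± 0.061) and Ccl2 (1.34 ± 0.506, 1.21 ± 0.16).

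Of 54 gene lists tested in TG, camera called 12, all higher in CTG, and 19 without CTG replicate 1. Over all genes tested, 0 members of these lists passed. Each of the 10 splits of the 6 TG libraries into 3 and 3 called at least 12 lists (highest other 28). The number of calls therefore does not tell the letters from other groupings. The list of glucocorticoid response genes was called at an adjusted p of 1.34e-13 (adjusted p = 0.898 with an estimated correlation). Of its 14 measured members, 13 had a higher mean in CTG, and 7 passed when adjusted over the list alone. The mean log2 difference was 0.53 and the median 0.38 (SD over members 0.58). Its examples beside Mt1 and Mt2 were Cdkn1a, a cell cycle inhibitor (49.1 ± 4.7 FPKM against 37.1 ± 3.3), and Sult1a1, a sulfotransferase (32 ± 2.06 against 26.5 ± 1.22). In all 3 CTG libraries the mean level of the list (4.50, 4.53 and 4.48 on the log2 scale) lay above all 3 STG libraries (4.05, 3.87 and 3.98).

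Markers of neutrophils and bone marrow, a tissue of the skull base next to the ganglion, were called higher as a list in CTG (12 of 12 members, mean log2 difference 2.27, adjusted p = 8.8e-09, 0 adjusted over the list alone). The granule proteases and peroxidase of immature granulocytes varied between libraries as much as their means, with Mpo at 10.1 ± 12.7 FPKM in CTG and 0.295 ± 0.201 in STG, Prtn3 at 6.01 ± 7.38 against 0.335 ± 0.149, and Elane at 7.36 ± 9.17 against 0.192 ± 0.197. Retnlg stood at 9.9 ± 9.54 against 0.445 ± 0.402. The list level was 5.29, 1.02 and 3.60 in CTG and between 0.44 and 1.36 in STG, so that CTG replicate 2 lay within the STG range. Without CTG replicate 1 the mean difference was 1.41. Bone and cartilage genes were called too (8 of 9 higher, mean 0.82, adjusted p = 4.14e-05, 1 adjusted over the list alone), with Dmp1 at 3.16 ± 2.76 against 0.823 ± 0.26, and stood at 0.41 without that library. With an estimated correlation, adjusted p = 0.898 for each of these 2 lists and for each of the 9 lists that follow. Too few neutrophil genes, 4, were measured in Sp5C for a test there.

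Acute phase and reactive glia genes were called (14 of 15 higher, mean 0.50, adjusted p = 4.01e-05, 0 adjusted over the list alone), with the iron-binding protein Lcn2 at 23.2 ± 27.3 FPKM against 1.65 ± 0.695, complement C3 at 9.62 ± 8.58 against 2.42 ± 0.367, S100a10 at 232 ± 14.5 against 203 ± 4.53 and Timp1 at 1.5 ± 0.487 against 0.827 ± 0.101. Without CTG replicate 1, the library with the highest bone marrow level, this list stood at a mean of 0.13 (adjusted p = 0.12). Complement genes (10 of 13 higher, mean 0.27, adjusted p = 0.0312) included C4b at 22.2 ± 3.71 against 16.7 ± 2.17, and were at 0.05 (adjusted p = 0.44) without that library, 0.29 (0.116) without CTG replicate 2, 0.18 (0.181) without STG replicate 2 and 0.48 without CTG replicate 3, and not called after median-ratio scaling (0.0515). Replication-dependent histones (13 of 15, mean 0.30, adjusted p = 0.000617), with Hist1h4i at 11.0 ± 1.5 against 7.69 ± 2.75, were at 0.18 without CTG replicate 1 (adjusted p = 0.27) and without STG replicate 3. Cell cycle genes (12 of 13, mean 0.18, adjusted p = 0.045), with Rrm2 at 2.31 ± 1.4 against 1.04 ± 0.245 and Mki67 at 4.76 ± 3.43 against 2.99 ± 0.785, turned to −0.06 without CTG replicate 1, were not called without STG replicate 1 (0.0948) or 2 (0.11, 0.167), and stood at 0.28 and 0.32 without CTG replicate 2 or 3, and were not called after median-ratio scaling (0.0588) or with a pseudocount of 0.1 (0.0575). In these 3 lists 0 members passed when adjusted over the list alone.

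Genes of protein synthesis and folding were called with small differences. Ribosomal protein genes had higher means for 24 of 25 members (mean 0.17, adjusted p = 1.85e-06, 1 adjusted over the list alone). Their mean was 0.29 without STG replicate 1, 0.09 without STG replicate 2 and 0.26 without CTG replicate 2. Endoplasmic reticulum stress genes had higher means for 15 of 15 (mean 0.16, adjusted p = 5.31e-05), among them the degradation factor Herpud1 (21.3 ± 1.29 FPKM against 17.6 ± 1.27), the chaperone Hspa5 (94.7 ± 6.01 against 84.2 ± 3.54) and the transcription factor Atf4 (44.2 ± 1.76 against 39.9 ± 1.82), and stood at 0.07 without CTG replicate 1. Heat shock genes (11 of 14, mean 0.16, adjusted p = 0.00652), with Hspa1a at 6.88 ± 3.05 against 3.34 ± 0.18, were not called without CTG replicate 3 (0.07, adjusted p = 0.378) and stood at 0.235 without CTG replicate 1. Oxidative phosphorylation genes (20 of 23, mean 0.08, adjusted p = 0.000675), with Sdhb at 57.2 ± 2.36 against 51.3 ± 0.466 and Uqcrb at 74.5 ± 3.97 against 66.8 ± 1.75, were at 0.01 (0.68) and 0.12 without these libraries. After quantile normalization neither list was called (0.151 and 0.148). Neuropeptide genes (10 of 10, mean 0.18, adjusted p = 0.00652), with Calcb at 27.9 ± 1.23 against 24.9 ± 1.26, were at 0.11 (0.15) without STG replicate 3, 0.13 (0.165) without CTG replicate 2 and 0.10 without CTG replicate 3. These last 4 lists had 0 members past the threshold when adjusted over the list alone.

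Several lists close to the study's question were not called in TG. Peptidergic nociceptor genes had a mean log2 difference of 0.07 (7 of 10 higher, adjusted p = 0.0739), nerve injury and regeneration genes 0.08 (9 of 13 higher, 0.246), satellite glia genes −0.05 (9 of 12 lower, 0.392), and microglia and macrophage genes 0.07 (10 of 19 higher, 0.449). Cytokine and chemokine genes had a mean of 0.06 but a median of −0.01 over 15 members (adjusted p = 0.846). Peptidergic nociceptor genes were called at 0.12 without STG replicate 2 (adjusted p = 0.00148) or without CTG replicate 3 (0.000818), and microglia and macrophage genes at 0.20 (0.0114) without the latter. Pituitary genes, from a gland beside the ganglion, had lower means in CTG for 7 of 7 members (mean −1.48, adjusted p = 0.0739), with the hormone subunit genes Cga at 0.267 ± 0.38 FPKM against 47.2 ± 79.1 and Lhb at 0.0182 ± 0.0316 against 7.06 ± 11.7. The pituitary level was 6.10 in STG replicate 1 and between 0.32 and 1.65 in the other TG libraries. The pituitary list was called without STG replicate 2 (−2.56, adjusted p = 0.00148) or 3 (−2.22, 0.0057), whereas without STG replicate 1 the difference over the same members turned to 0.33 (4 of 7 higher).

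**Figure D2:**
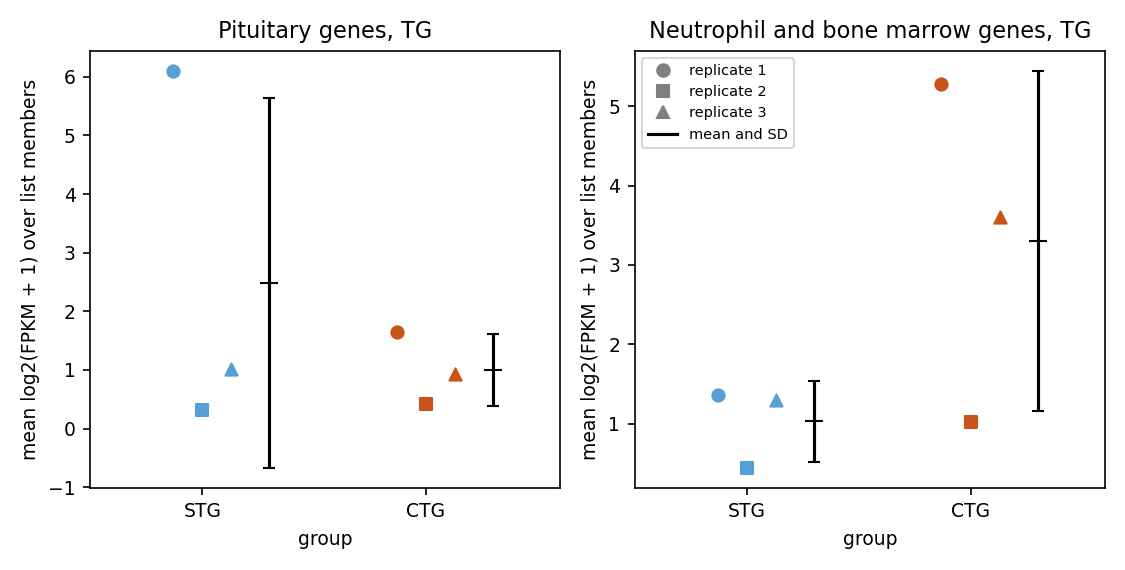
Mean log2(FPKM + 1) of pituitary genes (left) and of neutrophil and bone marrow genes (right) in the 6 TG libraries, with group means and SD as bars, which can reach below 0. Pituitary genes stand out in STG replicate 1 (6.10) and bone marrow genes in CTG replicates 1 (5.29) and 3 (3.60).

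The comparison of CSp5C with SSp5C asks the same of the brainstem nucleus. There, 4 of 12690 genes passed limma's test. The gene 2810474O19Rik (ENSMUSG00000032712, chromosome 6, 149309414 to 149335663, plus strand) rose from 3.31 ± 0.43 FPKM in SSp5C to 7.82 ± 0.502 in CSp5C (log2 difference 1.04, adjusted p = 0.0398), above all SSp5C libraries in 3 of 3. The other 3 passed as listed at 0 in all CSp5C libraries. Mrps10, a mitochondrial ribosomal protein (ENSMUSG00000034729, chromosome 17, 47368887 to 47381417, plus strand, adjusted p = 0.00879), was at 3.67, 5.49 and 6.22 in SSp5C. Prm1, a protamine that packs sperm DNA (ENSMUSG00000022501, chromosome 16, 10796326 to 10805839, minus strand, 0.00879), was at 2.23, 2.44 and 2.06, and Tnp1, a transition protein of spermatids (ENSMUSG00000026182, chromosome 1, 73015074 to 73015909, minus strand, 0.0149), at 1.83, 2.58 and 2.09.

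A further protamine, Prm2, was listed at 0 in CSp5C and at 1.31, 2.29 and 2.47 FPKM in SSp5C (adjusted p = 0.0895). In TG these sperm genes did not follow the letter, as Prm1 and Tnp1 were at 0 in STG replicate 1 and CTG replicate 3 and above 0 in the other TG libraries. A total of 637 genes had an unadjusted p under 0.05, and the groups did not overlap for 10.9% of genes, against 10% by chance. The count of 4 was 0 without SSp5C replicate 2, 1 without SSp5C replicate 1, 7 without CSp5C replicate 1 and 8 without CSp5C replicate 3. The call of 2810474O19Rik ended without any one of the 6 libraries, with adjusted p between 0.0551 and 0.327, and also without a filter (0.0724), with a mean FPKM of at least 5 (0.120), without genes listed at 0 throughout a group (0.158) and without trend (0.0507). In the fit of all 12 libraries the 4 genes were at 0.804 to 0.896. Mrps10 was at 0.0747 without SSp5C replicate 2, and Tnp1 at 0.0585 without CSp5C replicate 2.

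Among genes that did not pass in Sp5C, Gvin1, an interferon-inducible GTPase, stood at 4.66 ± 0.615 FPKM in CSp5C and 2.12 ± 0.187 in SSp5C (adjusted p = 0.134), Hax1, an anti-apoptotic mitochondrial protein, at 25.7 ± 2.23 against 16.7 ± 1.02, Net1 at 8.62 ± 0.0619 against 6.03 ± 0.283, and Gm4070 at 5.66 ± 0.952 against 2.26 ± 0.4 (0.168 each). Ddit4, a glucocorticoid-induced inhibitor of mTOR, stood at 25.1 ± 2.72 against 17.3 ± 0.629, and Acer2, a ceramidase, at 4.74 ± 0.349 against 2.56 ± 0.447 (0.365 each). Chd2 (17.4 ± 0.733 against 12.8 ± 0.929), Cbll1 (3.69 ± 0.38 against 2.04 ± 0.304) and Taok3 (13.5 ± 0.274 against 10.9 ± 0.156) had adjusted p of 0.382 to 0.482. With lower means in CSp5C, Sez6l stood at 18.8 ± 0.502 against 26.2 ± 0.664 and Btf3, a transcription factor, at 46.5 ± 2.73 against 68.0 ± 2.47 (0.0895 each). Gm12355 (0.2 ± 0.0437 against 3.2 ± 1.35), Fam173a (20.2 ± 2.07 against 31.4 ± 1.48), Zfp68 (7.12 ± 0.818 against 12.1 ± 1.05) and Tmem151a (36.9 ± 0.175 against 56.1 ± 6.77) had adjusted p of 0.127 to 0.207. Gfap of astrocytes (205 ± 97.8, 212 ± 12.8), Fos (9.07 ± 1.94, 7.94 ± 1.05), Aif1 of microglia (4.27 ± 3.27, 3.83 ± 0.822), Calca (11.4 ± 5.53, 9.27 ± 3.13) and Tac1 (22.2 ± 6.65, 26.6 ± 4.25) had adjusted p of 0.931 to 0.993.

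Of 56 gene lists tested in Sp5C, camera called 9 higher and 5 lower in CSp5C (8 lists in all without CSp5C replicate 1), with 0 members past the threshold over all genes. Each call ended with an estimated correlation (adjusted p = 0.978 with an estimated correlation for each of the 14). Of the 10 splits of the 6 Sp5C libraries into 3 and 3, the real one included, 8 called at least 14 lists (highest other 21). Glucocorticoid response genes had the smallest p, as in TG (adjusted p = 2.72e-17). All 15 measured members had a higher mean in CSp5C, by 0.56 on the log2 scale on average, and 13 passed when adjusted over the list alone. Tsc22d3, a direct target of the glucocorticoid receptor, stood at 66.2 ± 5.21 FPKM against 51.1 ± 2.08, Plin4, a lipid droplet protein, at 2.84 ± 1.12 against 0.825 ± 0.357, and Lcn2 at 3.02 ± 0.443 against 1.09 ± 0.535. The list level was 3.91, 4.32 and 4.01 in CSp5C and 3.49, 3.59 and 3.46 in SSp5C. The effects on this list in TG and Sp5C differed by −0.03 (adjusted p = 0.814).

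**Figure D3:**
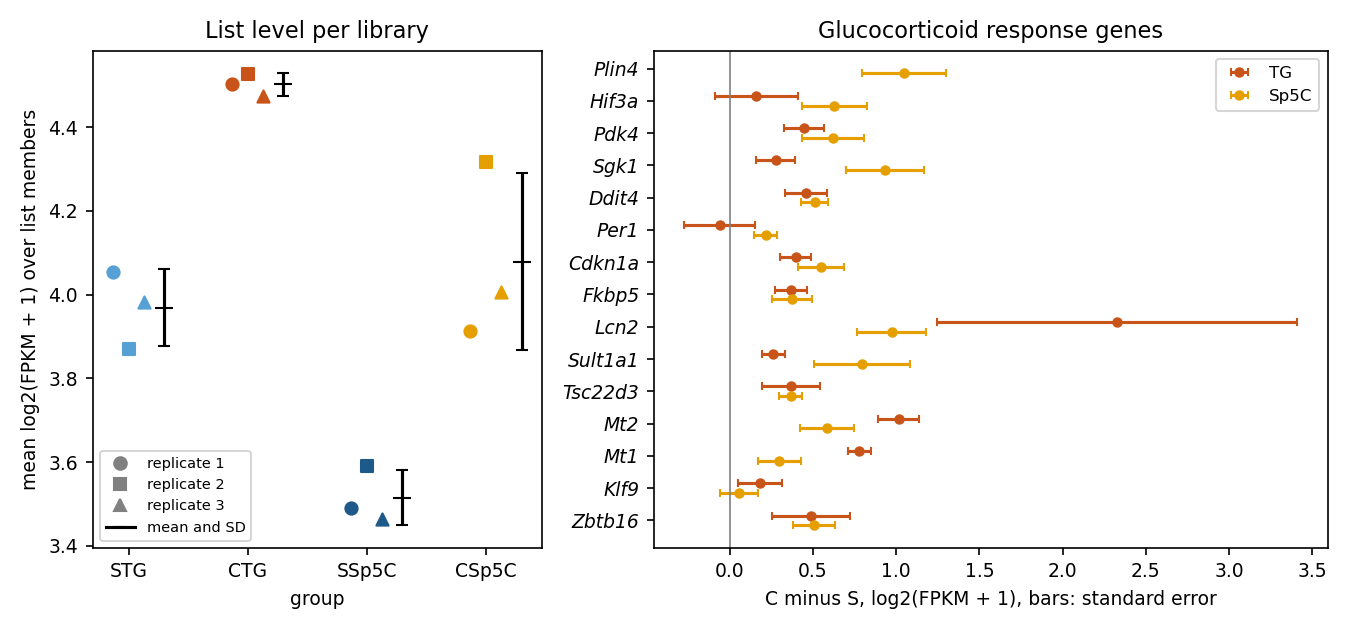
Left, mean log2(FPKM + 1) of the glucocorticoid response genes in each library (14 members in TG, 15 in Sp5C), with group means and SD. Right, C minus S difference of each member with its standard error; 13 of 14 lie above 0 in TG and 15 of 15 in Sp5C.

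Genes of oligodendrocytes, the myelin-forming cells of the brain, were called lower in CSp5C (15 of 15 members lower, mean log2 difference −0.31, adjusted p = 9.17e-14, 10 adjusted over the list alone). The lineage factors Olig2 (15.2 ± 0.439 FPKM against 18.7 ± 0.376) and Olig1 (58.3 ± 3.33 against 73.9 ± 7.3), the connexin Gjc3 (35.1 ± 2.13 against 42.9 ± 2.93), the myelin protein Mbp (674 ± 84.1 against 817 ± 24.8) and Opalin (14.3 ± 3.29 against 21.3 ± 2.11) were among them. The list's level was 6.92, 6.87 and 6.60 in CSp5C and 7.13, 7.10 and 7.09 in SSp5C. CSp5C replicate 3, with the lowest of these levels, had the highest level of cerebellum genes (3.70, others 2.79 to 3.18), and hindbrain HOX genes were lower in CSp5C for 14 of 14 members (−0.23). In TG, where Schwann cells form the myelin, 13 of 13 measured members of the list had lower means in CTG by 0.19 on average without a call (adjusted p = 0.075), and the effects of both tissues did not differ past the threshold (0.0622). Myelinating Schwann cell genes, several of which oligodendrocytes share, were called lower in CSp5C (8 of 9, −0.23, adjusted p = 0.000474, −0.11 without CSp5C replicate 3), as were cholesterol synthesis genes (14 of 18, −0.08, 0.000474), with Sqle at 33.2 ± 0.814 against 37.2 ± 1.66. Adjusted over the list alone, 0 members of both passed.

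Interferon response genes were called higher in CSp5C (17 of 20, mean 0.33, adjusted p = 0.000419), with Stat2 at 5.93 ± 0.295 FPKM against 4.86 ± 0.243, Gbp3 at 7.2 ± 2.99 against 3.52 ± 0.719 and Igtp at 7.76 ± 5.54 against 2.58 ± 0.702. So were MHC class I genes (10 of 11, 0.35, 0.00217), with the peptide loading factor Tapbp at 16.8 ± 1.51 against 14.3 ± 0.67. The interferon list was at 0.25 (adjusted p = 0.077) without CSp5C replicate 1 and 0.16 (0.0813) without replicate 2, and the MHC class I list at 0.17 (0.193) and 0.18 (0.112). Without CSp5C replicate 3 both were higher, at 0.59 and 0.70, and without SSp5C replicate 1 the MHC class I list stood at 0.18. Heat shock genes were called higher (12 of 14, 0.22, 0.00217), with the co-chaperone Dnajb1 at 17.4 ± 2.47 against 13.9 ± 0.553, and were at 0.13 (0.051) without CSp5C replicate 3 and 0.34 without CSp5C replicate 1. Acute phase and reactive glia genes (7 of 9, 0.21, 0.0303, 1 adjusted over the list alone), with S100a10 at 17.3 ± 2.23 against 14.2 ± 1.26, were not called without SSp5C replicate 1 (0.13, 0.0558) or 3 (0.20, 0.143) or without CSp5C replicate 1 (0.09, 0.353), and stood at 0.38 without CSp5C replicate 3. In the interferon, MHC class I and heat shock lists 0 members passed when adjusted over the list alone.

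Lists of neighbouring tissue and of vessels and membranes were called in part, and endothelial (mean 0.11, adjusted p = 0.391), choroid plexus (0.42, 0.579) and ependymal genes (0.11, 0.943) were not. Cerebellum genes were called higher (11 of 11, mean 0.41, adjusted p = 0.000474), with the granule cell GABA receptor subunit Gabra6 at 2.91 ± 2.86 FPKM against 0.268 ± 0.12. They were at 0.09 (0.411) without CSp5C replicate 3. Hindbrain HOX genes were called lower (14 of 14, −0.23, 0.00292), with Hoxd4 at 6.71 ± 0.896 against 8.15 ± 0.387 and Hoxa5 at 25.1 ± 6.55 against 30.2 ± 2.14, and were at −0.11 (0.102) without CSp5C replicate 1, −0.385 without replicate 2 and −0.19 (0.212) without replicate 3. Fibroblast and meninges genes were called higher (14 of 16, 0.52, 0.00541), with Mgp at 22.3 ± 6.24 against 10.9 ± 8.86 and a list level of 3.86, 3.65 and 2.70 in CSp5C and 2.35, 3.84 and 2.44 in SSp5C, but not without SSp5C replicate 1 (0.26, 0.166) or 3 (0.31, 0.311) or CSp5C replicate 1 (0.30, 0.331) or 2 (0.40, 0.136), and stood at 1.01 without SSp5C replicate 2 and 0.88 without CSp5C replicate 3. Pericyte and smooth muscle genes were called higher (6 of 9, 0.27, 0.0164, 2 adjusted over the list alone), with Myh11 at 6.56 ± 0.984 against 3.81 ± 0.61, Tagln at 8.26 ± 0.653 against 4.3 ± 1.44 and Acta2 at 12.7 ± 1.68 against 7.35 ± 2.88, but not without SSp5C replicate 1 (0.17, 0.0994) or CSp5C replicate 1 (0.18, 0.314). Adjusted over the list alone, 0 members of the cerebellum, HOX and fibroblast lists passed.

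Mitochondrially encoded genes were called higher in CSp5C (13 of 13, mean 0.31, adjusted p = 0.00841), with mt-Nd5 at 1948 ± 244 FPKM against 1577 ± 510.0. Their level was 10.65 in SSp5C replicate 1 and between 11.45 and 11.80 in the other Sp5C libraries, and the difference was −0.02 without SSp5C replicate 1 and 0.48 without SSp5C replicate 2. They were not called without CSp5C replicate 1 (0.21, adjusted p = 0.227) or after quantile normalization (0.11, 0.409). Excitatory brainstem neuron genes were called lower (10 of 11, −0.20, 0.0371), with Sst at 74.5 ± 14.4 against 86.4 ± 3.2, but stood at −0.12 (0.34) without SSp5C replicate 2, 0.01 (0.797) without CSp5C replicate 1 and −0.315 without CSp5C replicate 2, and were not called after quantile normalization (0.051). In both lists 0 members passed when adjusted over the list alone. Astrocyte genes (mean −0.05 over 13, adjusted p = 0.552), microglia and macrophage genes (0.08 over 19, 0.714), inhibitory brainstem neuron genes (−0.02 over 11, 0.579) and cytokine and chemokine genes (−0.0037 over 10, 0.552) were not called in Sp5C. The microglia and macrophage list was called at 0.43 without CSp5C replicate 3 (adjusted p = 1.33e-07) and turned to −0.28 without CSp5C replicate 1, and the astrocyte list was called at −0.11 (0.0251) without SSp5C replicate 1.

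The effects of the letter in TG and Sp5C were set against each other in 1 fit. No gene of 13081 differed in effect by limma's test (0 called, smallest adjusted p = 0.862, 708 at an unadjusted p under 0.05). The genes with the smallest p were Btf3 (difference of effects 0.82), Zfp68 (0.83), Igsf8 (0.94) and Tmem151a (0.61) on one side and Pln (−1.35), Usp53 (−0.57), Chd2 (−0.60), Prokr2 (−0.85) and Plekha7 (−0.66) on the other. Epo, which was listed at 0 in all CSp5C libraries, was at 1.45, 1.22 and 3.12 FPKM in SSp5C, 0.0857, 0.0682 and 1.83 in STG, and 4.99, 1.98 and 1.79 in CTG. Across 12072 genes, which are not independent replicates, the effects of both tissues correlated at r = 0.0770 (rho = 0.0102), between −0.00509 without STG replicate 2 and 0.139 without STG replicate 1.

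Annotated lncRNA as a class lay lower in CTG than in STG and higher in CSp5C than in SSp5C. Median-ratio scaling within the class centres it and so removes such a shift by construction, whereas with scaling over protein-coding genes the median difference of effects between the tissues was −0.353 (−0.365 as deposited). In TG, 83.1% of 1373 tested genes had a lower mean in CTG (median log2 difference −0.22), while limma called 0 (331 at an unadjusted p under 0.05, 7 higher and 324 lower). The groups did not overlap for 32.5% of them, against 10% by chance. In Sp5C, 73.8% of 1402 had a higher mean in CSp5C (median 0.14), with 144 at an unadjusted p under 0.05. There the groups did not overlap for 15.6%, against 10% by chance. The class levels of the Sp5C groups overlapped, with SSp5C replicate 3 at 0.007 and CSp5C replicate 1 at −0.04. Of the genes tested in Sp5C, 1 was called. It was RP23-377G8.5 (ENSMUSG00000096751.3, chromosome 12, 102673017 to 102727333, minus strand), which rose from 0.00236 ± 0.00174 to 1.39 ± 0.121 FPKM (log2 difference 1.91, adjusted p = 0.000325, 3 of 3 libraries), but was not called in the fit of all 12 libraries (0.376). In TG it ranged from 0.00136 to 2.18, with low and high libraries in both groups. Of 1431 genes, 44 differed in effect between the tissues. That number was 28 with scaling over protein-coding genes, 0 without STG replicate 1, 234 without CSp5C replicate 1, and 0 with the TG and Sp5C library of one letter and number as a block (404 at an unadjusted p under 0.05). Without CTG replicate 2, 12 genes were called in TG, and without CSp5C replicate 1, 2 in Sp5C.

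Of the nuclear lncRNA looked up, Malat1, Neat1 and Miat did not pass in either tissue. In TG, Miat stood at 13.2 ± 3.28 FPKM in CTG and 24.2 ± 2.31 in STG (log2 difference −0.87, adjusted p = 0.0864), and was called without CTG replicate 2 (−1.05, 0.0307). Neat1, the scaffold of paraspeckles, stood at 87.8 ± 17.2 against 112 ± 11.2 (0.184), and Malat1 of nuclear speckles at 1647 ± 148 against 2031 ± 96.5 (−0.30, 0.135). In Sp5C, Malat1 stood at 1149.5 ± 99.9 in CSp5C and 987 ± 126 in SSp5C (adjusted p = 0.48), Neat1 at 42.6 ± 4.39 against 38.1 ± 5.96 (0.597) and Miat at 11.9 ± 4.54 against 9.997 ± 1.75 (0.762). Other annotated lncRNA with the smallest p in TG were RP23-71L21.6 (−0.93), RP23-277H6.1 (−0.71), RP23-457L16.2 (−0.95) and AC163434.5 (16.0 ± 0.653 against 23.6 ± 1.14), each with an adjusted p of 0.0864. Those with higher means in CTG, RP24-540G19.3 (0.46), RP23-73N16.7 (1.10), RP24-226L18.2 (0.38) and RP23-380K24.2 (0.45), did not pass either. In Sp5C, RP23-413D8.2 (0.78) and Gm26894 (−1.03) had an adjusted p of 0.453, as had RP23-339O7.1 (0.66), RP24-499C1.4 (0.65), RP24-329C11.12 (−0.54), RP23-128M23.2 (−0.82), RP23-430N15.2 (−0.64) and RP23-223C15.2 (−0.48). RP23-128M23.2 was called without CSp5C replicate 1 (−1.11, 0.00726), and RP23-71L21.6 and RP23-457L16.2 in TG without CTG replicate 2 (0.0307 each).

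**Figure D4:**
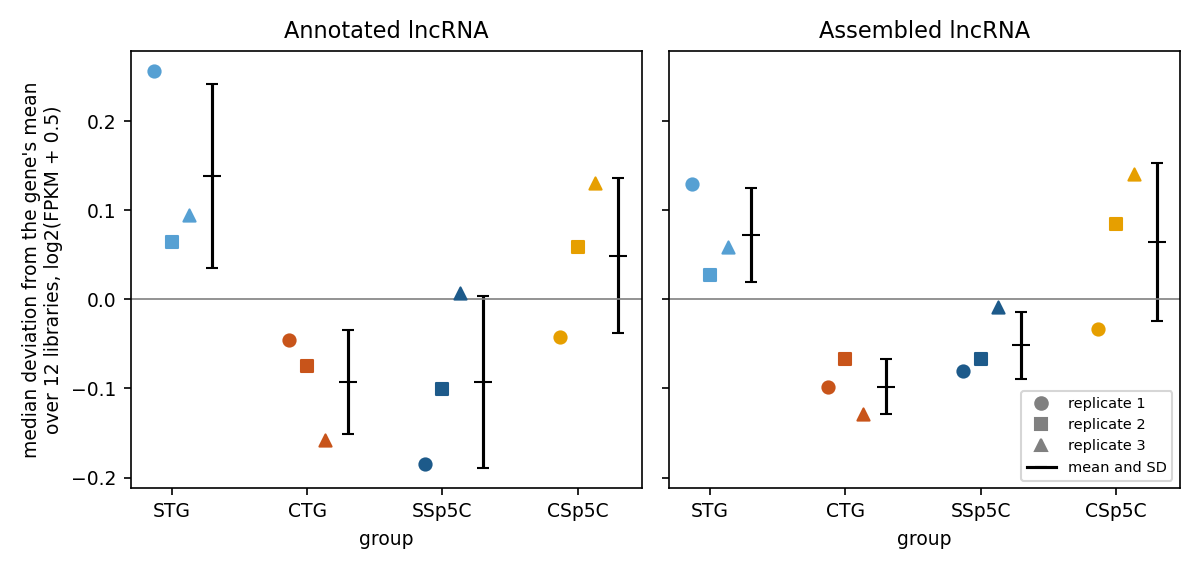
Median deviation of annotated (left) and assembled (right) lncRNA from each gene's mean over 12 libraries, log2(FPKM + 0.5), per library with group means and SD. Annotated lncRNA lie at −0.05, −0.07 and −0.16 in CTG against 0.26, 0.06 and 0.09 in STG. The Sp5C groups overlap, at −0.04, 0.06 and 0.13 in CSp5C against −0.19, −0.10 and 0.007 in SSp5C.

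Assembled lncRNA had medians on the same sides as annotated lncRNA, with fewer loci behind them. In TG, 74.0% of 496 loci had a lower mean in CTG (median −0.17), the groups did not overlap for 27.6% against 10% by chance, and limma called 0 (86 at an unadjusted p under 0.05). XLOC_006228 stood at 0.953 ± 0.333 FPKM in CTG and 0.217 ± 0.118 in STG, and XLOC_108720 at 0.267 ± 0.0785 against 1.3 ± 0.435 (adjusted p = 0.22 each). In Sp5C, 65.6% of 482 had a higher mean in CSp5C (median 0.09), and the groups did not overlap for 13.3%, against 10% by chance. There limma called 0 (26 at an unadjusted p under 0.05, against 24.1 by chance). XLOC_181328 stood at 4.1 ± 0.242 in CSp5C and 1.95 ± 0.292 in SSp5C, XLOC_203302 at 36.4 ± 30.5 against 1.05 ± 0.78, and XLOC_154656 at 1.07 ± 0.711 against 3.16 ± 0.974 (adjusted p = 0.805 each). Without CSp5C replicate 2, XLOC_203302 was called (adjusted p = 0.0194). The test of the difference between tissues was not run for assembled loci.

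Between tissues, all libraries of one tissue lay above all of the other for 32.8% of annotated and 27.0% of assembled lncRNA, against 0.216% by chance. Of 1431 annotated lncRNA, 433 were higher and 374 lower in TG, 132 and 130 of them by at least 1 on the log2(FPKM + 0.5) scale. Rmst, a lncRNA of neural development, stood at 0.448 ± 0.597 FPKM in TG and 26.7 ± 3.02 in Sp5C and Pantr1 at 0.193 ± 0.0923 against 8.29 ± 0.895, next to RP23-142A14.3 (−4.53). Higher in TG were RP23-442G9.5 (12.3 ± 0.672 against 0.0337 ± 0.0405), RP24-312B12.1 (20.8 ± 3.12 against 0.405), Sptbn5 (12.5 ± 4.07 against 0.146), AC163434.5 (19.8 ± 4.22 against 1.32 ± 0.094) and the imprinted H19 (24.0 ± 15.3 against 1.59 ± 1.26, adjusted p = 0.000359). Of 460 assembled loci, 95 were higher and 114 lower in TG. XLOC_159298 was listed at 0 in all 6 Sp5C libraries and at 4.95, 4.35 and 4.45 in STG and 5.50, 3.81 and 3.50 in CTG, XLOC_156063 stood at 3.26 ± 0.591 against 0.00511 ± 0.0125, and XLOC_207984 at 1.28 ± 0.764 against 19.5 ± 9.06.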

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

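Of the tests in this part, the comparison of annotated lncRNA effects between tissues, the alternatives for the lists that differ in effect between tissues, the test of the letters and the scaling by protein-coding genes for lncRNA, the tests of the letters and of failed estimates for spermatid genes, the splits and block that keep libraries of one letter and number together, and the tests of library scaling, of Mt1 and Mt2 and of the spermatid split for glucocorticoid response genes were chosen only after the result was seen.

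In a check of the mean level of each list over the 6 libraries of a tissue, 8 of 110 levels had 1 library apart from the rest, against 5.5 by chance, with the gap to the next library divided by the whole range above 0.625. Pituitary genes were highest in STG replicate 1 (gap over range 0.771). In CTG replicate 1, acute phase and reactive glia genes (0.691), endoplasmic reticulum stress genes (0.699) and cell cycle genes (0.660) were highest. In CTG replicate 3, excitatory brainstem neuron genes (0.792) and oxidative phosphorylation genes (0.685) were highest. In Sp5C, excitatory brainstem neuron genes were lowest in CSp5C replicate 1 (0.651) and mitochondrially encoded genes lowest in SSp5C replicate 1 (0.698).

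The C minus S difference of 12 lists differed between TG and Sp5C by camera with a preset correlation, and of 0 with an estimated correlation (smallest adjusted p = 0.970, and 0.986 by fry). Relative to Sp5C it was higher in TG for neutrophil and bone marrow genes (by 2.23 on the log2 scale, which repeats the TG difference, since 4 of these genes were measured in Sp5C), bone and cartilage genes (0.702), replication-dependent histones (0.372), excitatory brainstem neuron genes (0.298), hindbrain HOX genes (0.225, which repeats the Sp5C difference with its sign turned, since 0 of them were measured in TG), endoplasmic reticulum stress genes (0.169), ribosomal protein genes (0.0973) and oxidative phosphorylation genes (0.0866). It was lower in TG for interferon response genes (−0.422), mitochondrially encoded genes (−0.367), cerebellum genes (−0.313, with 4 of them measured in TG) and collagen and extracellular matrix genes (−0.278). Without CTG replicate 1, over the same members, the difference in TG was 1.28 (SD over members 0.591) for neutrophil and bone marrow genes, where 4 of 12 had all CTG libraries above all STG libraries, and 0.42 (SD 0.380) for bone and cartilage genes, with 4 of 9. Each of the 12 calls ended in fits without at least 1 library, for neutrophil (1.25), bone (0.281), cerebellum (−0.339), HOX (0.220), interferon (−0.379), endoplasmic reticulum (0.0818), ribosomal (0.0462) and histone genes (0.264) without CTG replicate 1, for cerebellum (−0.278), excitatory (0.218), interferon (−0.247), collagen (−0.160), oxidative phosphorylation (0.0202) and mitochondrial genes (−0.290) without CTG replicate 3, for interferon genes (−0.127) without STG replicate 1, mitochondrial (−0.309) without STG replicate 2, and cerebellum (−0.254) and collagen genes (−0.120) without STG replicate 3, for collagen (−0.127) and mitochondrial genes (−0.0414) without SSp5C replicate 1, excitatory (0.208) and HOX genes (0.186) without SSp5C replicate 2, and cerebellum (−0.289) and collagen genes (−0.213) without SSp5C replicate 3, and for excitatory (0.0968), HOX (0.106), interferon (−0.340), collagen (−0.190) and mitochondrial genes (−0.273) without CSp5C replicate 1, interferon (−0.247) and collagen genes (−0.192) without CSp5C replicate 2, and cerebellum (−0.180) and HOX genes (0.185) without CSp5C replicate 3. Called values that moved by over 1.5 times were those of ribosomal genes (0.215, 0.0225 and 0.0549 without STG replicate 1, 2 or 3, 0.192 and 0.0541 without CTG replicate 2 or 3, 0.0574 without CSp5C replicate 2), interferon genes (−0.697 without STG replicate 3, −0.642 without CTG replicate 2, −0.680 without CSp5C replicate 3), collagen genes (−0.425 without STG replicate 2, −0.493 without SSp5C replicate 2, −0.452 without CSp5C replicate 3), neutrophil genes (3.43 without CTG replicate 2), histones (0.242 without STG replicate 3) and HOX genes (0.383 without CSp5C replicate 2). After quantile normalization oxidative phosphorylation (0.0106), mitochondrial (−0.170) and ribosomal genes (0.0149) were not called, and with a pseudocount of 0.1 cerebellum (−0.387) and HOX genes (0.297) were not.

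Glucocorticoid response genes were higher in C than in S in both tissues. Over the 14 members measured in both, the difference averaged 0.53 on the log2 scale. The values argue against library scaling, which would move other genes alike. The median difference of the other genes in the list's range of levels was 0.00893 or less in absolute value in each tissue (SD over genes 0.194 in TG and 0.161 in Sp5C). The values also argue against attached tissue in CTG replicate 1 or STG replicate 1 alone, since the TG difference was 0.575 without both (0.533 with all). CTG replicate 3, with a neutrophil and bone marrow list level of 3.60, stayed in that fit. The fit therefore cannot exclude a part of attached marrow in that library. Mt1 and Mt2 were not the only members that moved, since 91.7% of the others (11 of 12) were positive in both tissues. That share follows from the signs of the whole list, and the weight of single members in its mean was not tested. The spermatid split of the libraries did not account for the TG part, where the difference was 0.589 among libraries with those transcripts, but in Sp5C 0 libraries part that split from the letter, so both cannot be told apart there. With the letters reassigned in each tissue separately, 0.5% of 200 relabelings, only the real one, gave as large a difference as the real 0.531, the highest other being 0.424. That is the smallest share this test can give, and it takes no account of the number of lists tested. With libraries of one letter and number kept together across the tissues, the 10 splits are too few for a share under 0.05 (highest other 0.239). The list's calls within each tissue also ended with an estimated correlation. A difference in glucocorticoid signalling between the animals of C and S is therefore a hypothesis that stays open, beside handling or time of dissection, which the labels do not give.

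Annotated lncRNA were lower in CTG than in STG and higher in CSp5C than in SSp5C as a class, and 44 of 1431 differed in effect between tissues. Over the 12 libraries, the deviation of annotated lncRNA from the group mean rose with that of assembled lncRNA (r = 0.887, rho = 0.909, exact permutation within groups p = 0.00154 for both from 1296 permutations, and r = 0.869 without STG replicate 1 and SSp5C replicate 3), in line with a property of whole libraries, such as the share of nuclear or unspliced RNA, as a candidate explanation. The scaling of the libraries is argued against for the median difference of effects, since the ratios of protein-coding genes that scaling divides by were 0.969 to 1.02 and the median was −0.353 with it (−0.365 as deposited), but the count of genes fell from 44 to 28 with it, so its part in that count stays open. With the letters reassigned in each tissue separately, 1% of 200 relabelings gave as large a median difference as the real 0.365 (highest other 0.370). Of 100 relabelings, 1, the real one, gave as many genes (44, highest other 3). Both values argue against chance labels as long as the libraries of both tissues are independent. However, CTG and CSp5C libraries of one number deviated together (r = 0.333, 0.228 and 0.383). STG and SSp5C libraries did not, and with 3 libraries per group such a match can also arise by chance. With libraries of one letter and number kept together the 10 splits are too few for a share under 0.05 (median difference 0.365, highest other 0.293, and 44 genes, highest other 1). With letter and number as a block 0 genes were called, at the same median absolute difference of the 44 genes (0.956) but a median standard error of 0.242 (0.221 without the block) and 4 residual degrees of freedom (8 without), and a biological effect of the letter and a difference in RNA preparation between the groups both remain open.

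The spermatid genes Prm1, Prm2, Tnp1 and Tnp2 were listed at 0 in STG replicate 1, CTG replicate 3 and all CSp5C libraries and above 0 in the other 7, where Prm1 was at 2.06 to 3.44 FPKM and Tnp2 at 1.10 to 1.95. A difference between C and S is argued against, since 3 libraries go against the letter. Of 29 other spermatid genes, 28 (96.6%, 95% binomial interval over genes 82.2% to 99.9%) had a higher mean in the 7 libraries than in the other 5, against 55.7% of 3822 genes of the same range of mean level. The interval treats the genes as independent and measures no spread between libraries. Of the 21 of these 29 genes that were above 0 in some of the 5 libraries, 20 were lower there even where above 0. The shares of 28 of 29 and 20 of 21 argue against failed estimates of single genes. The 96.6% is consistent with a trace of testis RNA or of its reads in those 7 libraries, a hypothesis; the step at which it entered was not tested, nor was a biological explanation beyond the letter.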

How the results depend on the processing

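Some alternatives were chosen only after the data were seen, namely fits without genes listed at 0 throughout a group, without both first TG libraries (CTG and STG replicate 1), without both unusual Sp5C libraries (SSp5C replicate 1 and CSp5C replicate 3), with the spermatid split as a batch term or with scaling over protein-coding genes, and every alternative of the comparison over both tissues, of the annotated lncRNA and gene list effects between tissues and of the correlation of effects. Over all settings other than leaving out 1 library, named genes and lists kept direction and side of the threshold in 2387 cases, fell short of it in 115, passed it in 29 and turned in 15, the last given here. With 1 library left out the numbers were 1656, 73, 14 and 29. Cases that passed in neither setting and kept direction count as kept. Many named genes and lists did not pass, so these numbers do not measure how stable the calls were. Counts stayed within 1.5 times, and the correlation of effects within 1 SD, in 132 cases and moved further in 52 (111 and 44 with 1 library left out, where 1 more turned). Where a value changed and its setting does not itself remove genes or libraries, the cause was not tested. The depth of the libraries is unknown, so its limits could not be assessed. The tissue contrast of protein-coding genes stayed within 1.5 times of its count in each alternative.

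For protein-coding genes in TG (1 called), 0 were called with a mean FPKM of at least 5, 0 in the fit of all 12 libraries, 0 without genes listed at 0 throughout a group, 2 after quantile normalization, 7 with library weights, 12 transcripts with each transcript as its own feature and 5 without both first TG libraries. Leaving out 1 library gave 0 to 7. In Sp5C (4 called), 0 were called with a mean FPKM of at least 5, in the fit of all 12 libraries and without genes listed at 0, and 9 with library weights, and leaving out 1 library gave 0 to 8. For the difference of effects (0 called), 2 transcripts were called as features of their own, and leaving out 1 library gave 0 to 2. Over both tissues (2 called), 0 were called with a pseudocount of 5, without a filter and on means of the TG and Sp5C library of one letter and number, 1 with a mean FPKM of at least 5 and 1 without trend, 4 after quantile normalization and 9 with library weights, and leaving out 1 library gave 0 to 8.

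With the replicate number as a block, 0 protein-coding genes were called in TG, 0 in Sp5C and 0 annotated lncRNA differed in effect between tissues. The other counts that were run with the block stayed within 1.5 times. It was not run for the comparison over both tissues, where means of the TG and Sp5C library of one letter and number took the count of genes from 2 to 0. The numbers did not pair C with S libraries or STG with SSp5C libraries, but CTG and CSp5C libraries of one number deviated together. With 3 libraries per group such a match can also arise by chance. Correlations of same-numbered libraries' deviations from their group means were 0.0894, 0.191 and −0.151 for CTG with STG, −0.127, 0.0659 and 0.103 for CSp5C with SSp5C, 0.333, 0.228 and 0.383 for CTG with CSp5C, where each library correlated best with its own number, and −0.0803, −0.197 and −0.0227 for STG with SSp5C, where none did.

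For annotated lncRNA in TG (0 called), 17 were called with a mean FPKM of at least 2, 13 in the fit of all 12 libraries and 2 as single transcripts, and leaving out 1 library gave 0 to 12. In Sp5C (1 called), 0 were called with a mean FPKM of at least 2 and 0 in the fit of all 12 libraries, 2 with library weights, and 1 to 2 with a library left out. For the difference of effects (44), 26 were called with a pseudocount of 2, 0 without a filter, 13 with a mean FPKM of at least 2, 0 after median-ratio scaling, 0 after quantile normalization, 199 with library weights and 28 with scaling over protein-coding genes, and leaving out 1 library gave 0 to 234. Between tissues (807), 1246 were called without a filter and 239 with a mean FPKM of at least 2. For assembled lncRNA in Sp5C (0), 1 was called with a mean FPKM of at least 2, and 0 to 1 with a library left out. Between tissues (209), 786 were called without a filter, 23 with a mean FPKM of at least 2 and 106 in C libraries alone. Filters change how many features are tested.

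Of gene lists in TG (12 called), 0 were called with an estimated correlation, 0 by fry and 23 without both first TG libraries, and leaving out 1 library gave 12 to 19. In Sp5C (14 called), 0 were called with an estimated correlation and 0 by fry, and leaving out 1 library gave 8 to 18. Over both tissues (14 called), 0 were called with an estimated correlation and 1 by fry, 0 and 0 by these on means of the TG and Sp5C library of one letter and number, and leaving out 1 library gave 11 to 20. For the difference of effects (12 called), 0 and 0 were called by these, 6 without CTG replicate 1, 19 without CSp5C replicate 3 and 9 to 17 without others. In TG, the microglia and macrophage list was at −0.011 without both first libraries and −0.107 to 0.198 with a library left out, the cell cycle list at −0.0497 and −0.0586 to 0.324, the satellite glia list at −0.153 to 0.0101, and the cytokine and chemokine list at −0.0138 to 0.136. In Sp5C, the cytokine and chemokine list was at 0.0156 after quantile normalization, 0.14 without both unusual libraries and −0.149 to 0.246 with a library left out. The ranges with a library left out were −0.111 to 0.0317 for astrocyte genes, −0.277 to 0.432 for microglia and macrophage genes, −0.315 to 0.0058 for excitatory and −0.0836 to 0.0868 for inhibitory brainstem neuron genes, and −0.0201 to 0.482 for mitochondrially encoded genes. The correlation of effects was −0.00509 to 0.139.

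Among single genes in TG, Tac1 turned to −0.00134 after quantile normalization, Aif1 to 0.0347 with library weights and Fos to 0.111 without both first libraries. With a library left out, Tac1 was at −0.0455 to 0.181, Aif1 at −0.237 to 0.224, Fos at −0.393 to 0.122, Mki67 at −0.0585 to 0.65, Gfap at −0.552 to 0.245 and Ccl2 at −0.108 to 0.17. In Sp5C, Aif1 turned to 0.017 with a pseudocount of 5 and 0.321 without both unusual libraries, Calca to −0.218 with library weights and −0.295 without both unusual libraries, and Gfap to 0.33 without the latter. With a library left out, Aif1 was at −0.519 to 0.376, Calca at −0.099 to 0.624 and Gfap at −0.493 to 0.288. After median-ratio scaling within annotated lncRNA, which moves the whole class together, Malat1 in TG was at 0.0227, and Neat1 and Miat in Sp5C at −0.0363 and −0.014. With a library left out, Miat was at −0.0657 to 0.497 in Sp5C.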

Other observations

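Of the tests in this part, the comparison over both tissues, with its splits, and the tissue contrast of annotated lncRNA effects were chosen only after the data were seen.

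Gene lists set out the make-up of the ganglion and the nucleus. In TG, all 12 measured pan-sensory neuron genes rose relative to Sp5C (mean log2 difference 2.71, adjusted p = 6.34e-06), as did 14 of 15 non-peptidergic nociceptor genes (2.27, 6.34e-06), 9 of 10 peptidergic nociceptor genes (3.59, 3.24e-05) and 19 of 22 collagen and extracellular matrix genes (2.11, 6.34e-06). Of the immune lists, MHC class I (11 of 11 rose, 1.36, 0.0109), MHC class II (6 of 6, 2.15, 0.0188) and interferon response genes (20 of 21, 1.47, 0.000249) were called higher in TG, whereas microglia and macrophage (5 rose and 4 fell, 0.14, 0.854), complement (0.67, 0.258), neutrophil and bone marrow (1.45, 0.187) and cytokine and chemokine genes (−0.06, 0.978) were not called. Of 21 genes of TRP, ASIC, P2X, HCN and Piezo channels, which open to heat, acid, ATP, voltage or touch, 17 rose and 4 fell (1.44, 0.00176). Myelinating Schwann cell genes (9 rose and 5 fell, mean 2.59, 0.0658) and large myelinated sensory neuron genes (8 rose and 4 fell, 0.96, 0.161) were not called. Satellite glia genes, written as markers of glia of the ganglion, were called lower in TG (3 rose and 8 fell, −1.03, 0.0495). In Sp5C, 14 of 14 hindbrain HOX genes were higher (−3.21, 1.43e-07), as were 10 of 11 inhibitory brainstem neuron genes (−3.42, 6.34e-06), 12 of 13 astrocyte genes (−3.17, 6.34e-06), 13 of 15 oligodendrocyte genes (−2.45, 5.66e-05), 15 of 17 ionotropic glutamate receptor genes (−1.49, 2.21e-05) and 21 of 23 oxidative phosphorylation genes (−0.42, 8.84e-05). Of 59 lists, camera called 27 and fry 49, and with an estimated correlation 0 were called (smallest adjusted p = 0.261).

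Averaged over both tissues, 2 of 13081 genes fell in C. Gm12355, a predicted gene (chromosome 11, 98624351 to 98625661), fell by 1.68 on the log2 scale (adjusted p = 0.0201), with the C libraries at 0.289 ± 0.0941 FPKM in TG and 0.2 ± 0.0437 in Sp5C and the S libraries at 3.07 ± 1.57 and 3.2 ± 1.35. Fam173a, a mitochondrial lysine methyltransferase (chromosome 17, 25790080 to 25792901), fell by 0.50 (adjusted p = 0.0294), from 23.8 ± 1.56 to 18.1 ± 1.45 in TG and from 31.4 ± 1.48 to 20.2 ± 2.07 in Sp5C. For both genes, all C libraries lay below all S libraries of their tissue. Next were Mt2 (0.80) and Mt1 (0.54), at an adjusted p of 0.0795 each, Plxnb3 (−0.32, 0.104), and Ddit4 (0.48) and Ube2a (0.62) at 0.182. The count of 2 was 8 without CTG replicate 1, 0 without CTG replicate 3, and 0 on means of the TG and Sp5C library of one letter and number (596 genes at an unadjusted p under 0.05). In Sp5C, Mt2 stood at 159 ± 33.0 in CSp5C against 105 ± 10.6 (adjusted p = 0.904 in limma's test). Mt1 stood there at 212 ± 37.2 against 171 ± 4.3, with overlapping groups (0.931). In TG, Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 14.4 ± 1.92 in CTG against 10.9 ± 0.585 in STG (0.96). None of these differences passed within its tissue. Of 59 lists camera called 14, and the glucocorticoid response list was higher for 15 of 15 members (0.55, 3.46e-24, 13 adjusted over the list alone), with an adjusted p of 0.0168 by fry and 0.0635 with an estimated correlation. On means of the TG and Sp5C library of one letter and number, camera still called it, but not fry (0.375) or camera with an estimated correlation (adjusted p = 0.796).

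Other divisions of the same libraries were counted for each test. The 10 splits of the 6 libraries of a tissue are too few for a share under 0.05. For protein-coding genes in TG, 8 of 10 splits called as many as the real split (1, highest other 6), and in Sp5C 3 of 10 (4, highest other 56). The latter split, CSp5C replicates 1 and 2 with SSp5C replicate 2 against the rest, called many times the real number, which points to a structure among the Sp5C libraries other than the letter. The level of fibroblast and meninges genes was 3.86, 3.65 and 3.84 in these 3 libraries and 2.35, 2.44 and 2.70 in the rest. For lists, 10 of 10 splits in TG (12, highest other 28) and 8 of 10 in Sp5C (14, highest other 21) called as many. For annotated lncRNA in Sp5C, 4 of 10 did (1, highest other 5; 144 at an unadjusted p under 0.05, highest other 269). For annotated lncRNA in TG and assembled lncRNA in both tissues the real count was 0, which 10 of 10 splits reach whatever the data (highest other 2, 2 and 1). At an unadjusted p under 0.05 the real split had 331 annotated lncRNA in TG (highest other 87), and 86 assembled lncRNA in TG (highest other 24) and 26 in Sp5C (highest other 52).

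With 100 relabelings of the letter within tissues, chance was not excluded for the genes of both tissues (13 gave as many as 2, highest other 104) or for the correlation of effects (66 gave as large an r as 0.0770, highest other 0.344). For the difference of effects of protein-coding genes the real count was 0, which all 100 reach whatever the data (highest other 26), and 29 relabelings gave as many genes at an unadjusted p under 0.05 as the real 708 (highest other 1310). With 100 relabelings of the tissue within letters for TG against Sp5C, 1 of them, the real one, called as many protein-coding genes (9314, highest other 0), annotated lncRNA (807, highest other 386) and assembled lncRNA (209, highest other 25). That is the smallest share 100 relabelings can give. These values argue against chance labels as long as the libraries are independent.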
